A study of Mus musculus with 2 samples.

How the data were processed

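RNA was sequenced from mouse neural stem cells, the self-renewing cells that give rise to neurons and glia, after transfection with a small interfering RNA (siRNA) against Chd4 (siChd4) or with a scrambled control siRNA (siSCR). Per the labels, total RNA was extracted with a commercial kit and libraries followed a standard Illumina protocol. The age and source of the cells, the siRNA sequence, its dose and the time after transfection are not given in the sources used here. Each group held 1 library, and groups were taken from the treatment labels.

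The authors deposited 1 table of 17359 genes with symbols and Entrez numbers. Per the file headers, it holds FPKM (fragments relative to transcript length and library size), TPM (transcript abundance scaled to a fixed total) and read counts for each library. The deposited counts are estimated counts, since 16.0% of the values in siSCR and 17.8% in siChd4 were whole numbers. The deposited TPM values sum to 1000000 in each library, and the deposited FPKM values are a constant multiple of them within a library, to rounding. The genome build was mm39, per the submitters' processing notes. The aligner, the counting tool, their versions, the use of strand and the removal of duplicate reads are not given in the sources used here. The table holds 24 symbols written as dates, as spreadsheet programs do, and 2 symbols that are held by more than 1 row. None of these was named.

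The main measure was the log2 ratio of siChd4 over siSCR on TPM plus a pseudocount of 1, over the 12882 genes with a mean TPM of at least 1. A ratio on this scale understates the difference of low genes, so folds of TPM are given beside it. Limits of 1.5-fold, 2-fold and 4-fold are on the TPM plus 1 scale. TPM was taken as the main unit among the authors' normalized values because it has the same total in both libraries. With 1 library per group there was no test between conditions. Each fold has an exact Clopper-Pearson 95% interval, computed from the estimated counts rounded to whole numbers. Intervals cover counting error only, and reads without molecular identifiers are not independent molecules. The libraries held 19817038 estimated counts (siSCR) and 20072209 estimated counts (siChd4), so a floor of 3 counts was 0.151 and 0.149 CPM. Transcript length was taken as the ratio of estimated counts to FPKM. It differed by more than 1.2 times between the libraries, relative to other genes, for 133 genes, whose TPM folds therefore differ from their count ratios.

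Genes were named by a rule fixed before the data were examined. The rule took Chd4, Chd3, Chd5, Cdkn1a and Seh1l, and the 12 highest and 12 lowest log2 ratios among genes with a mean TPM of at least 5, leaving out symbols of the Gm and Rik kinds for predicted genes, pseudogenes and mitochondrial genes. The rule did not leave out LOC symbols. It also took up to 3 members per direction of each gene list that passed a 1.5-fold difference, or the 2 most abundant members where none did, and the 5 most abundant genes. Some genes that the rule takes are not reported here. The 31 gene lists were fixed before the data were examined too. They cover cell types of the neural lineage, other cell types a culture may hold, cell cycle, p53 and stress responses, metabolism, signalling pathways, and the NuRD and nuclear pore complexes. Each list's median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, which describes these libraries only. Genes of 1 pathway vary together, so a list of them passes the 2.5th or 97.5th percentile more often than random lists do. Further lists were chosen after the values were seen: granins and dense-core vesicle cargo, tubulins, metallothioneins, actin cytoskeleton and serum response factor targets, SWI/SNF subunits, the Chd family, and known targets of the repressor REST.

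The alternatives fixed in advance were a pseudocount of 0.1, median-of-ratios and upper quartile scaling, no filter or a mean TPM of at least 5, 1.5-fold and 4-fold limits, 5 bins, the mean of a list, and CPM from the counts with TMM scaling. Alternatives added after the data were seen were FPKM, subtraction of the trend with transcript length (lowess, span 0.3), random lists matched also on length or on length and GC content, the counting interval as a filter, and leaving out the 133 genes above. The use of TMM scaling for Chd4, the lists and the named genes was also added then. A planned comparison with fold changes or p-values of the authors was not run, because no such columns were analysed here.

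For the closing section, 16681 of the 17359 Entrez numbers were matched to a GENCODE M21 transcript of the mouse GRCm38 assembly. That assembly differs from the mm39 build of the table, so it was used for sequences and for the place of 1 sequence only. All words of 7 bases in the longest annotated 3′ untranslated region (UTR) of each gene were set against the log2 ratio. Lengths, GC content and expression were allowed for by regression. The result was compared with 100 shuffles of the residuals within bins of UTR length. The word analysis covered 10502 genes with a mean TPM of at least 5 and a 3′ UTR of at least 100 bases.

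The steps were tested on simulated data. Of 200 genes simulated as 3-fold different among 12866 genes, in both directions, 99.0% of the higher and 89.0% of the lower genes were called 2-fold different, with 6 false calls. The counting interval held the true fold for 95.1% of genes. Of simulated lists without a shift, 5.5% lay outside the 2.5th to 97.5th percentiles, and all lists shifted by 0.3 did. Apart from the planted changes, the simulated libraries differed by counting error alone. They held no spread between cultures and no differences in transcript length, so these rates do not carry over to the real libraries. The versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, which was used for the TMM factors alone.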

Results

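The data are gene expression profiles of mouse neural stem cells that received a scrambled siRNA (siSCR, 1 library) or an siRNA against Chd4 (siChd4, 1 library). The series concerns Seh1, a subunit of the nuclear pore complex, in neurogenesis, and this part asks what follows from lowering Chd4, the ATPase of the NuRD chromatin remodelling complex. The siSCR library held 19817038 estimated counts and 16605 genes above 0. The siChd4 library held 20072209 estimated counts and 16656 genes above 0. The most abundant transcripts were Eef1a1, a translation factor, at 12588 TPM in siChd4 and 11353 TPM in siSCR, Ckb (8678 and 8528 TPM), the radial glia fatty acid binding protein Fabp7 (7004 and 6105 TPM), Tmsb4x (7758 and 4157 TPM) and the actin gene Actg1 (5200 and 3397 TPM). There are no replicates, so every difference below is between these libraries and has no check against the spread between cultures.

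Chd4 (Entrez 107932), the target of the siRNA, was at 203 TPM in siChd4 and 250 TPM in siSCR, a fold of 0.815 (95% counting interval 0.795 to 0.837) and a log2 ratio of -0.29. The direction follows the label, but the difference was small: 19.4% of the 12882 genes had a lower log2 ratio. Among 193 genes with a similar level and transcript length, the median log2 ratio was -0.19 and 30.6% lay below Chd4. After the trend with transcript length was subtracted, the log2 ratio of Chd4 was -0.14. The paralogs Chd3 and Chd5, which are alternative ATPases of NuRD, were higher in siChd4. Chd3 was at 18.7 against 6.19 TPM (3.02-fold, 2.67 to 3.41) and Chd5 at 19.1 against 4.65 TPM (4.11-fold, 3.65 to 4.63). Of the 15 NuRD subunits, these paralogs were the 2 past a 1.5-fold difference. The list's median was -0.02 (58.3rd percentile of matched random lists) and its mean 0.18, which was at the 99.0th percentile. Seh1l, which encodes Seh1, was at 34.9 TPM in siChd4 and 44.5 TPM in siSCR (0.783-fold, 0.715 to 0.858).

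More genes were higher than lower in the siChd4 library. At least 2-fold differences were found for 291 higher and 81 lower genes of 12882, and 183 of the higher genes were below 5 TPM in siSCR. With a pseudocount of 0.1 the numbers were 472 and 174, and at a 1.5-fold limit 868 and 576. On FPKM values they were 179 and 38, and with a mean TPM of at least 5 they were 170 and 55. Counting error alone gave at most 7 genes per direction in 100 simulated pairs of libraries. The middle 50% of log2 ratios lay between -0.24 and 0.17, with a median of -0.04. The libraries correlated across genes with a Pearson r of 0.979 and a Spearman rho of 0.981, where genes are not independent replicates. Longer transcripts had lower ratios: across genes the Spearman rho with length was -0.18, and the median log2 ratio was 0.01 in the shortest 10% of genes and -0.21 in the longest 10%. With this trend subtracted, 327 genes were at least 2-fold higher and 72 lower.

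**Figure D1:**
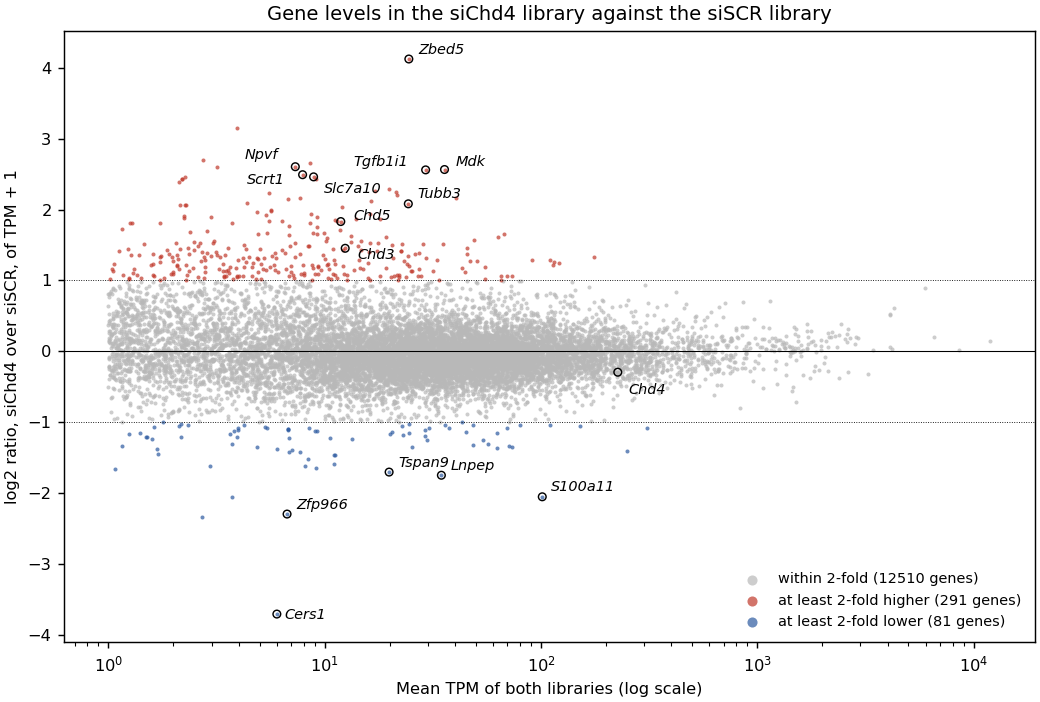
Log2 ratio of siChd4 over siSCR (TPM plus 1) against the mean TPM of both libraries (log axis) for 12882 genes, 1 point per gene. Dotted lines mark 2-fold differences, which 291 genes passed above and 81 below; Chd4 lies at -0.29, among the grey genes within 2-fold.

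The genes furthest above siSCR included several of neuronal and neuroendocrine cells. Tubb3, the neuronal tubulin, was at 40.0 against 8.70 TPM (4.60-fold, 3.76 to 5.67). The granins Scg2 (16.1 against 2.17 TPM) and Chgb (33.8 against 6.08 TPM), the secretory granule gene Resp18 (36.2 against 7.05 TPM), the neuropeptide gene Npvf (13.3 against 1.35 TPM) and Scrt1, a neural zinc finger repressor (14.1 against 1.69 TPM), were among the 12 highest. The others of the 12 were the growth factor gene Mdk (62.0 against 9.65 TPM), the focal adhesion gene Tgfb1i1 (50.8 against 7.79 TPM), the amino acid transporter gene Slc7a10 (15.7 against 2.04 TPM), Tmem179 (29.0 against 5.24 TPM), the purine receptor gene P2ry12 (36.1 against 6.84 TPM), Ly6h (9.77 against 1.29 TPM) and Zbed5. Zbed5 had a TPM fold of 26.7 but a count ratio of 6.13, because the transcript length behind its TPM differed between the libraries.

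As a group, neuronal genes were higher in siChd4. Their median log2 ratio was 0.41, above all 10000 matched random lists. Of 22 members with a mean TPM of at least 1, 8 were at least 1.5-fold higher and 0 lower, and 5 passed 2-fold. Besides Tubb3, Ina, a neurofilament gene, was at 34.3 against 11.4 TPM (3.01-fold, 2.64 to 3.45), and Dcx, of migrating immature neurons, at 10.9 against 3.71 TPM (2.93-fold, 2.54 to 3.38). The proneural and intermediate progenitor list was at the 86.0th percentile (median 0.05), with 3 of 14 members at least 1.5-fold higher: Dlx1 (14.3 against 7.06 TPM), Dlx2 (10.4 against 5.80 TPM) and Insm1 (43.6 against 26.9 TPM).

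Oligodendrocyte lineage genes were higher as a group too, with a median of 0.92, above all random lists. Of 14 members, 9 were at least 1.5-fold higher and 0 lower. Sox10, a transcription factor of the lineage, was at 7.71 against 1.05 TPM (7.34-fold, 4.69 to 12.02), and Cldn11 at 8.30 against 1.39 TPM (5.97-fold, 3.71 to 10.1). Olig1 and Olig2, chosen here after their values were seen, were abundant and nearly equal in the libraries, with log2 ratios of -0.01 and -0.02. Neural stem and radial glia markers had a median of -0.10 (17.2nd percentile). Of 26 members, 2 were at least 1.5-fold higher, Hopx (70.6 against 43.5 TPM) and Sox9 (81.1 against 51.0 TPM), and 2 lower, Gli3 (4.94 against 9.14 TPM) and Prom1 (4.72 against 8.37 TPM). Astrocyte genes had a median of -0.14 (5.56th percentile). Among them, Sparcl1 (1059 against 653 TPM) and Apoe (873 against 546 TPM) were higher. Lower were the gap junction gene Gja1 (40.8 against 105 TPM, 0.387-fold, 0.360 to 0.416), the cell surface receptor gene Cd44 (35.7 against 57.9 TPM) and the glutamate transporter gene Slc1a2 (58.4 against 94.1 TPM).

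Genes of mitosis and of the nuclear pore were lower in siChd4 by small amounts over most members. The G2/M list had a median of -0.35, below all 10000 random lists, and 29 of its 30 members were below 0. Ccnb1, the mitotic cyclin, was at 208 against 328 TPM (0.636-fold, 0.611 to 0.662), with Ccnb2 (0.641-fold) and Cenpf (0.642-fold) also past 1.5-fold. Nucleoporins had a median of -0.25 (0.06th percentile), with 27 of 29 members below 0. The 1 member past 1.5-fold was Ndc1, which anchors the pore in the membrane, at 34.5 against 90.2 TPM (0.383-fold, 0.357 to 0.410). DNA replication and S phase genes had a median of -0.13 (4.85th percentile, and 2.58th with length and GC content matched). Of 30 members, 27 were below 0 and 0 were past 1.5-fold, with Pcna at 811 against 912 TPM and Rrm2 at 609 against 725 TPM.

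Cdkn1a, the cell cycle inhibitor p21, was at 662 against 577 TPM (1.15-fold, 1.11 to 1.18). The CDK inhibitor list had a median of 0.11 (89.1st percentile) and 0 of 7 members past 1.5-fold. Its next most abundant member, Cdkn2c, was at 170 against 181 TPM. The p53 target list had a median of -0.03 (65.8th percentile), and 1 of its 30 members, Perp, passed 1.5-fold (12.8 against 6.64 TPM).

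Among metabolic groups, cholesterol synthesis genes were higher, with a median of 0.21 (99.99th percentile) and 17 of 20 members above 0. Dhcr7, of the last step of the pathway, was at 186 against 102 TPM (1.82-fold, 1.72 to 1.93). Cytosolic ribosomal protein genes had a median of 0.14 (99.9th percentile) and nuclear oxidative phosphorylation genes one of -0.17 (0.17th percentile). Each list had 0 of 30 members past 1.5-fold. Examples are Rps2 (4193 against 4016 TPM) and Rplp0 (2461 against 2116 TPM), and Atp5b (2368 against 2897 TPM) and Atp5a1 (1274 against 1438 TPM). Ribosomal protein genes have near-identical pseudogenes that can share their reads. Glycolysis and hypoxia genes had a median of -0.08 (26.8th percentile), with Ndrg1 (0.38 against 2.10 TPM) and Pdk1 (7.31 against 12.1 TPM) lower.

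Markers of other cell types were present at low levels. Fibroblast and smooth muscle markers had a median of 0.31 (98.4th percentile, and 95.4th with length and GC content matched), with Tagln (6.53 against 2.14 TPM) and Col1a1 (1.96 against 0.64 TPM) higher and Fn1 lower (10.6 against 16.9 TPM). Striated muscle genes had a median of 0.89 (99.9th percentile, and 97.3rd, within the middle 95%, with no filter on low values), and 5 of 7 members were at least 1.5-fold higher. Among them, Tnnt1 was at 6.60 against 2.64 TPM and the cardiac actin gene Actc1 at 4.08 against 0.21 TPM, from 48.0 and 2.37 counts (19.4-fold, 6.04 to 196). Myl1 had a TPM fold of 3.30 but a count ratio of 1.35. The microglia and macrophage list had 4 members above the limit (75.4th percentile, median 0.14), and P2ry12 was the 1 past 1.5-fold. Endothelial and pericyte markers (3 members, 67.1st percentile, median 0.25) included Eng (1.87 against 0.98 TPM) and Flt1 (1.53 against 1.31 TPM), and had 0 past 1.5-fold on the TPM plus 1 scale. The TPM fold of Eng was 1.91 (1.19 to 3.23). Ependymal and choroid plexus markers had a median of -0.22 (10.3rd percentile), with Enkur at 1.08 against 2.20 TPM, where the interval of 0.199 to 1.07 includes 1. Of the germline genes, 4 had a mean TPM of at least 1, with a median of -0.45 (1.31st percentile, and 5.20th with length and GC content matched), and Sycp3 was at 1.75 against 3.89 TPM. Of the Hox genes, 8 were listed and 0 reached that mean.

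Stress and signalling lists lay within the middle 95% of lists matched on expression. Immediate early genes, Wnt pathway genes and matrix genes lay outside it under some other settings. Interferon-stimulated genes, which foreign RNA can induce, had a median of -0.08 (29.6th percentile) and a mean of 0.005, and Ifit3 (2.41 against 0.94 TPM) was the 1 of 15 past 1.5-fold. Unfolded protein and integrated stress response genes had a median of 0.07 (92.6th percentile) and 0 of 22 past 1.5-fold, with Calr at 976 against 772 TPM and Hsp90b1 at 540 against 568 TPM. Heat shock genes had a median of 0.02 (65.2nd percentile), with Hspa1b at 1.62 against 0.63 TPM. Immediate early genes had a median of 0.13 (96.7th percentile), with Arc (71.8 against 41.7 TPM) and Fosl1 (2.10 against 0.98 TPM) higher and Fosl2 lower (3.53 against 5.97 TPM). The Wnt pathway list, of targets and ligands, had a median of -0.19 (7.28th percentile), with 9 of 13 members below 0 and 4 above. The ligand gene Wnt5a (12.9 against 26.2 TPM) and Rnf43 (1.06 against 2.20 TPM) were lower. Hedgehog pathway targets had a median of 0.07 (72.7th percentile) but a mean of -0.04, with Cdon at 26.4 against 40.5 TPM. Extracellular matrix and adhesion genes had a median of 0.09 (96.8th percentile, and 99.7th with length matched). Of 31 members, 5 were at least 1.5-fold higher, led by Ccn2 (18.6 against 5.0 TPM), Lama4 (17.4 against 7.01 TPM) and Lama2 (4.95 against 2.15 TPM), and 2 lower, Nid2 (8.57 against 16.9 TPM) and Itga1 (4.20 against 7.43 TPM).

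The genes furthest below siSCR did not form 1 of the fixed groups. S100a11, a calcium-binding protein gene, was at 38.8 against 164 TPM (0.237-fold, 0.197 to 0.284), and Lnpep, a membrane aminopeptidase gene, at 15.4 against 53.9 TPM (0.285-fold, 0.261 to 0.312). The tetraspanin gene Tspan9 (8.81 against 30.9 TPM), Parvb (5.04 against 17.2 TPM), Sh3bgrl2 (5.49 against 16.9 TPM), the potassium channel gene Kcnn3 (3.71 against 11.6 TPM), the transcription factor gene Zbtb20 (3.28 against 10.4 TPM) and LOC115489733 (5.42 against 16.7 TPM) were also among the 12 lowest. So was Zfp966 (1.61 against 11.8 TPM), which had a TPM fold of 0.137 but a count ratio of 0.207, because the transcript length behind its TPM differed between the libraries. The liver genes Alb (3.89 against 14.3 TPM) and Hpx (3.49 against 12.7 TPM) were among the 12 lowest too. Cers1 had 0.03 estimated counts in siChd4 and 254 in siSCR. It shares a transcript with Gdf1, which was higher in siChd4 (23.8 against 8.38 TPM). The counts of both genes summed to 531 in siChd4 and 431 in siSCR. How reads of the shared transcript were divided between the genes was not tested, so their separate values are uncertain. Of the replication-dependent histone genes, 2 had a mean TPM of at least 1, and H1f2 was at 92.8 against 143 TPM. Of the 13 protein genes of the mitochondrial genome, 0 were in the table as analysed here.

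Of the 28 lists with a percentile, 6 lay above and 4 below the middle 95% of random lists, where chance alone gives 1.4 outside it for lists of unrelated genes. With transcript length matched as well the numbers were 7 and 4, and with length and GC content 6 and 3.

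**Figure D2:**
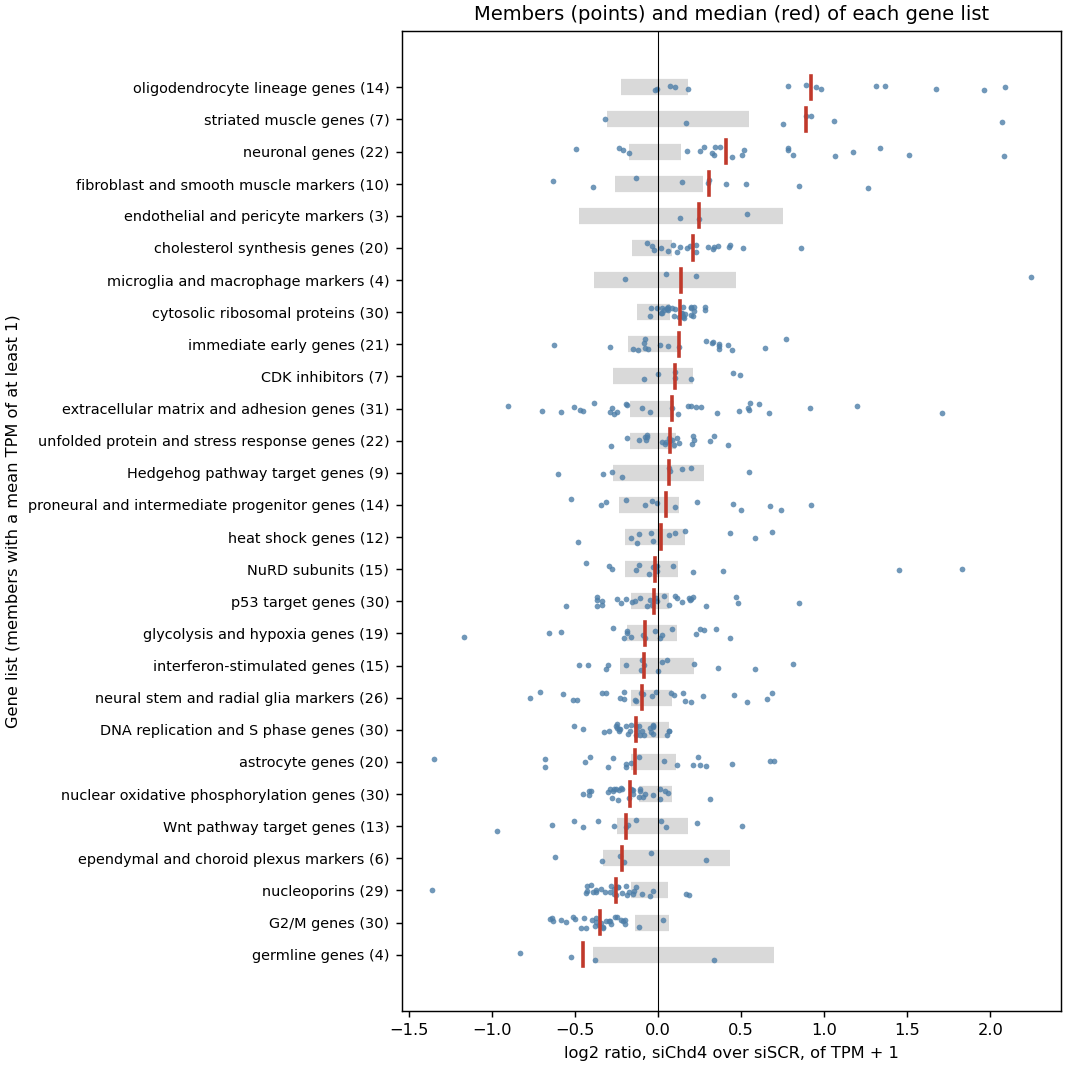
Log2 ratio of siChd4 over siSCR (TPM plus 1) of each member (points) of 28 gene lists, with the list's median as a red line and, in grey, the middle 95% of medians of 10000 random lists matched on expression. Oligodendrocyte, striated muscle and neuronal genes lie to the right of the grey range (medians 0.92, 0.89 and 0.41), and G2/M genes and nucleoporins to its left (-0.35 and -0.25).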

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

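FPKM values, the length trend, matching on length or GC content, the counting interval, and TMM scaling for Chd4, lists and named genes were alternatives chosen after the data were seen. The 93 named genes gave 465 values under other settings; none past 1.5-fold turned its sign, and 397 stayed within the counting error. The log2 ratio of Chd4 stayed below 0: it was -0.24 with median-of-ratios and upper quartile scaling, -0.23 on FPKM and -0.14 with the length trend subtracted. The genes past 2-fold numbered 472 higher and 174 lower with a pseudocount of 0.1, 179 and 38 on FPKM, 868 and 576 at 1.5-fold, and 30 and 5 at 4-fold. With a mean TPM of at least 5, 170 were higher. A smaller pseudocount widens ratios of low genes by construction. FPKM values were below TPM values (Eef1a1 at 5220 FPKM and 12588 TPM in siChd4), so the same pseudocount of 1 narrows ratios of low genes. FPKM also differs in its scaling between the libraries, which moved Chd4 up, from -0.29 to -0.23. Such a shift alone would not lower the number of higher genes. How much each part moved the numbers was not tested. Of 276 list percentiles, 259 stayed on their side of the limits. Fibroblast and smooth muscle markers were at 97.12 with no filter, 96.5 with a mean of at least 5, 92.66 by the mean of ratios and 95.37 with length and GC content matched. Striated muscle genes were at 97.26 with no filter, and germline genes at 3.17 by the mean and 5.20 with length and GC content matched. The cause of these list differences was not tested. Lists went outside the limits in 10 settings. With a mean TPM of at least 5, immediate early genes were at 99.84, matrix genes at 98.83 and astrocyte genes at 2.10. By the mean of ratios, NuRD subunits were at 98.99, microglia markers at 98.17, S phase genes at 1.42 and Wnt pathway genes at 2.36. Wnt pathway genes were at 2.11 with TMM scaling, and matrix genes at 99.67 with length matched and 98.39 with length and GC content matched. The comparison with authors' fold changes, and leaving out columns, were not run: there were no such values here, and 1 column per group. Depth limits genes near the floor of 3 counts. No paired analysis was possible because each group held 1 library.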

Other observations

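The tests of known REST targets, of added neurons, of 8-base sites, of seed words in separate genes, and of the strands of 1 siRNA were chosen after the results were seen, as were the additional gene lists below. The tests of length, of GC content and of 7-base words were chosen after the list medians were seen, but before their own results.

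Of 14 granins and dense-core vesicle cargo genes, 12 were at least 1.5-fold higher in siChd4 and 0 lower, with a median of 1.15 (100th percentile). The list was prompted by Scg2, Chgb, Resp18 and Npvf, and the other 10 genes had a median of 1.03 (100th percentile, 8 at least 1.5-fold higher). Examples are Chga (26.3 against 6.13 TPM), Vgf (13.2 against 2.17 TPM) and the prohormone convertase gene Pcsk2 (2.20 against 0.43 TPM). Actin cytoskeleton and serum response factor targets had a median of 0.61 (100th percentile, 17 genes, 9 at least 1.5-fold higher and 0 lower), and 0.37 (100th percentile, 12 genes, 4 at least 1.5-fold higher) without Tgfb1i1, Tmsb4x, Actg1, Ccn2 and Tagln, which were named above. Examples are Cnn2 (20.2 against 6.25 TPM) and Tpm2 (11.6 against 3.85 TPM), while Srf itself was at 24.9 against 26.3 TPM. Metallothioneins, the metal-binding proteins, were lower in all 3 genes of a list made after their values were seen (median -0.51, 0.10th percentile), led by Mt2 at 137 against 362 TPM. Tubulins were at the 91.4th percentile (median 0.09), with Tubb4a at 67.0 against 14.3 TPM and Tuba1c at 13.7 against 32.3 TPM. SWI/SNF subunits were at the 60.3rd percentile (median -0.03). Of the 9 Chd family genes, 7 were below 0 (median -0.21, mean 0.15). Their percentile was 10.5 with expression matched, 63.0 with length matched as well and 34.4 with length and GC content. Chd1 was at 0.680-fold and Chd9 at 0.780-fold, and Chd3 and Chd5 were the 2 above 0.

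The higher neuronal genes were weighed against a length trend, a larger share of neurons and release of genes held by REST, a repressor of neuronal genes. The length trend was excluded as the whole cause, since the list stayed at the 100th percentile with length matched. Known REST targets outside the neuronal list had a median of 1.18 (21 genes), partly from granins that prompted the test. The 16 without the granins and named genes had a median of 0.69 (9 at least 1.5-fold higher and 0 lower, 100th percentile). That was 0.35 above the median of the 17 neuronal genes that are not known targets (0.34). Those 17 genes were also high, at the 99.94th percentile (4 at least 1.5-fold higher and 0 lower), so the difference was not confined to known REST targets. Rest itself was at 10.7 against 17.0 TPM (0.629-fold, 0.567 to 0.698). Weaker repression by REST is a candidate explanation. More neurons in the siChd4 culture cannot be told apart from it: of the 5 neuronal genes below 5 TPM with at least 30 counts in siSCR, 4 had a counting interval above 1, and the cells of each culture were not counted by type here. An effect of Chd4 and any other difference between these 2 cultures stay open, because each group held 1 library.

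The slightly lower G2/M genes and nucleoporins may reflect fewer dividing cells in the siChd4 culture, a hypothesis that was not tested on cells. Transcript length was excluded as the whole cause, since with length matched the G2/M list stayed below all random lists, at a percentile of 0, and nucleoporins at 0.19. With length, expression and GC content matched the percentiles were 0 and 0.64. Ndc1, at 0.383-fold, lies far from the other nucleoporins. Culture density and harvest time stay open.

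Some of the genes lower in siChd4 carry a signature that off-target silencing by the siRNA could give, through pairing of its seed (bases 2 to 8) with 3′ UTRs. Of 15666 words of 7 bases, 3 went with lower ratios beyond the lowest of 100 shuffles (z of -4.68) and 0 with higher ones: CACAACA (z = -6.40), CCACAAC (z = -6.32) and CTCTCAG (z = -5.85), and they stayed the 3 lowest words without the genes 2-fold lower (z of -5.71, -5.29 and -5.38). In 98 of 100 overlapping splits, the 3 lowest words of a random 50% of genes went with lower residuals in the other genes. The median difference was -0.039. Of the 50 genes 2-fold lower with a 3′ UTR analysed, 17 held an 8-base site, CCACAACA or CTCTCAGA. S100a11, Tspan9 and Zbtb20 were among these 17. In 100 sets matched on UTR length the median was 5 and the highest number 11. CCACAACA joins CCACAAC and CACAACA. CTCTCAGA joins CTCTCAG and TCTCAGA, and TCTCAGA (z = -4.27) was not beyond the lowest shuffle. The sites came from words scored on genes that include these 50, so the count of 17 is not an independent test. CCACAAC occurs in the Chd4 transcript, as do 30.2% of the words tested, but it lies there beside the reverse complement of CTCTCAG at the spacing that the strands of 1 siRNA of 19 base pairs would have, in the sequence CCTGAGAGGTTCCACAACT, and 5 of 16681 transcripts, Chd4 included, hold such a window of any of the 3 words. That sequence is coding and spans exons 18 and 19 of 39 of Chd4 (GRCm38 chromosome 6, 125109160 to 125109173 and 125109292 to 125109296, plus strand). It is a candidate for the siRNA used, which the labels do not give. Among the 16681 transcripts, Chd4 ranked 3 by the lowest sum of both z, and the search did not allow for transcript length.

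The 3′ UTR of Rest, of 3451 bases, held 0 of both 8-base sites and 0 of the 3 7-base words, while CTCTCAGA occurred 1 time elsewhere in its transcript.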
